A study of Sus scrofa with 24 samples.

How the data were processed

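Gene expression was measured in subcutaneous adipose tissue of 24 pigs at 115 kg body weight on Agilent one-colour arrays (Cy3), with 8 pigs per group and 1 array per pig, per the labels. The groups were a low residual feed intake line with free access to feed (RFIneg), a high residual feed intake line with free access to feed (RFIpl) and the high line given the feeding level of the low line (RFIplR). Residual feed intake is the feed an animal eats beyond what its growth and maintenance predict.

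The deposited scanner files hold spot intensity values made with Feature Extraction 10.7.3.1, per the file headers. The processed intensity in them is background-subtracted and spatially detrended but not scaled between arrays, per the file headers. The deposited table of processed values holds log2 values of 24582 probes from the same arrays. Set against the scanner files, its columns were log2 of the processed intensity centred on each array's median, with the same direction (column medians no farther than 0.001 from 0, SD of the difference at most 4.5e-10). The rule that chose its probes is not given in the sources used here. R 2.10.0 is named in the submitters' processing notes.

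Values were log2 of the processed intensity, with a floor of 1, minus the 75th percentile of the non-control probes of each array. Control spots and non-uniform spots were left out, and spots of one probe were averaged. A probe was kept when it was well above background on at least 6 of the 8 arrays of at least 1 group and missing on no more than 6 arrays. Of 43603 probes, 28606 were kept. A symbol was assigned to 12240 probes, of which 7187 were matched by accession and 1366 by gene identifier to a RefSeq gene table of the Sscrofa11.1 assembly, used for names only, while 3592 kept the symbol in the files and 95 were named from the description in the files. A further 35 probes had several symbols and 31328 had none, and neither kind was named. The kept probes held 4388 symbols. 1 gene of the panel is not reported here. No spot was saturated and no pair of arrays was identical. The number of arrays limits the precision.

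The 3 pairwise comparisons and a test of any group difference came from one limma 3.58.1 fit over all 24 arrays (lmFit and eBayes, R 4.3.3), with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. All p-values given for single genes are adjusted p-values of limma and two-sided. Version 1.17.8 of data.table read the files, and pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9 and Python 3.11.15 were used for annotation and figures. Of 36 gene lists fixed beforehand, 35 were tested with camera at a preset inter-gene correlation of 0.01, on the probe of each gene with the highest mean signal. The list of sex-linked transcripts was not tested, since none of its 2 probes was kept. Camera compares a list with all other genes. The fry test, run beside it, asks whether the genes of a list move, on balance, one way, without comparing them with other genes. Median differences of a list are over its measured genes.

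The groups, the fit, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule took, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among called probes with 1 symbol, or the 3 with the smallest p where none passed. It also took the 4 members with the smallest p in the direction of each list past the camera test, and a panel of 12 genes of fat metabolism at the probe with the highest mean signal. Where a gene had several probes, a called gene was given at its called probe with the largest change. For the called genes named here, all kept probes of the gene had the same sign in that comparison. The size could differ between probes. In RFIneg against RFIpl the 2 probes of CLDN3 stood at -4.45 and -0.63 and the 2 of SH3GL3 at -1.49 and -0.88. The 20 probes of CA3 lay between 2.07 and 2.59. Among the other named genes some probes went the other way. In RFIneg against RFIplR the same sign was found in 5 of 6 probes for NDUFB8 and IGF2, 8 of 9 for DLD, 1 of 2 for LEP and 6 of 8 for ADIPOQ, and in RFIplR against RFIpl in 1 of 2 for ACACA, 4 of 5 for LPL and 5 of 6 for IGF2.

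The arrays fell into 17 bright and 7 dim ones, a split found in the 75th percentile of the signal and not in any gene. The fit with this brightness class as a block, the fits within each class and within each scan day, the fits with slide and brightness together and the fits and list tests with RFIpl 2, RFIpl 3 or RFIpl 1 and 2 left out and the list tests with RFIpl 7 and 8 left out were added after the data were seen. A batch value is given within a slide or scan day where it held both groups. The alternatives chosen beforehand were a block for the replicate number, normexp background correction with an offset of 50, quantile and median scaling, other filters on dim probes, the deposited value table, a trended and robust variance, array weights, slide or scan day as a block, a fit of only the compared groups, other thresholds and leaving out each array.

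The fits were tested on simulated data for 28606 probes with 100 probes changed at each size. Without a block, a log2 change of 1 was recovered in 19% of the changed probes for RFIneg against RFIpl, in 29% for RFIneg against RFIplR and in 25% for RFIplR against RFIpl. A log2 change of 2 was recovered in 70%, 74% and 73%. With brightness as a block the shares were 79% in each comparison for a change of 1, and 99%, 98% and 99% for a change of 2. The simulated values held an additive effect of brightness and independent noise, both sized from the fit with brightness as a block. A gain from the block was thus built in, and the shares do not give the recovery on the real arrays.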

Results

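Transcripts of subcutaneous adipose tissue were compared between 3 groups of 8 pigs at 115 kg. The comparison of RFIneg with RFIpl asks how the lines differed when both had free access to feed, that of RFIneg with RFIplR how they differed at one feeding level, and that of RFIplR with RFIpl what the lower feeding level did within the high line.

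The arrays differed strongly in brightness. On 17 arrays the 75th percentile of the processed intensity lay between 414 and 663, and on 7 arrays between 69.4 and 94.4. The dim arrays numbered 2 in RFIneg, 2 in RFIpl and 3 in RFIplR, and all 7 were scanned on the day that held 10 arrays. The median signal of the spike-in control probes was 33.6 to 46.2 on the dim arrays and 223 to 998 on the bright ones. Between 43.1% and 79.9% of probes were well above background on an array. Over the kept probes, bright arrays correlated with each other at 0.936 to 0.991 and with dim arrays at 0.769 to 0.825, and the first principal component held 74.6% of the variance. The arrays lay on 7 slides and were scanned on 3 days, which held 11, 10 and 3 arrays. On day 1 there were 5 RFIneg, 3 RFIpl and 3 RFIplR arrays, on day 2 there were 2, 4 and 4, and on day 3 each group had 1.

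**Figure D1:**
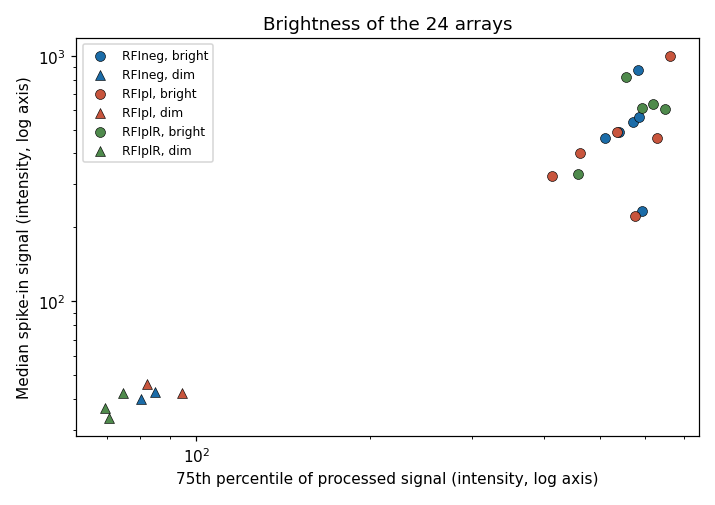
Median spike-in signal against the 75th percentile of processed signal, both as intensity on log axes, for each of the 24 arrays. The 7 dim arrays (triangles) lie at 69.4 to 94.4 on the horizontal axis and the 17 bright arrays (circles) at 414 to 663.

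In RFIneg against RFIpl, both with free access to feed, adipose tissue of the low line had more transcript of CES1, a carboxylesterase that hydrolyses esters, and of CA3, a carbonic anhydrase abundant in fat cells and muscle. It had less of CLDN3, a tight junction protein of epithelia. CLDN3 fell by 4.45 on the log2 scale (SE 0.66, adjusted p = 0.0161), from a mean of 0.73 in RFIpl to -3.72 ± 1.12 (SD, n = 8) in RFIneg, and was well above background on 8 RFIpl, 4 RFIneg and 5 RFIplR arrays. Its other kept probe was not called and changed by only -0.63. CES1 rose by 3.33 (SE 0.63, adjusted p = 0.0275), from 2.30 ± 1.92 to 5.63 ± 0.58 (SD, n = 8 each). CA3 rose by 2.59 (SE 0.49, adjusted p = 0.0275). Each of the named genes called in this comparison lay beyond the RFIpl mean in 8 of 8 RFIneg arrays, which their choice from these same arrays favours.

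Other genes that rose in RFIneg encode calcium-binding proteins of neutrophils and monocytes, S100A8 (log2 change 2.18, adjusted p = 0.0452) and S100A12 (1.90, adjusted p = 0.0417). They were the 2 risen members of the inflammatory response list, which did not pass as a list (adjusted p = 0.776 in camera). S100A8 was well above background on 7 of 8 RFIpl arrays and on all others. MYOC, a secreted glycoprotein, rose by 2.07 (adjusted p = 0.0275). UCP3, a carrier of the inner mitochondrial membrane, rose by 1.57 (adjusted p = 0.046) and was the 1 risen gene of 13 in the list of mitochondrial uncoupling, which did not pass (adjusted p = 0.776). MOCS1, of molybdenum cofactor synthesis, rose by 1.25 (adjusted p = 0.0436) and FHL1, a LIM domain protein, by 1.11 (adjusted p = 0.0331). Genes that fell were SH3GL3, an endophilin (-1.49, adjusted p = 0.0275), RFC4, a subunit of the clamp loader of DNA replication (-1.19, adjusted p = 0.0317), and P311 (-1.05, adjusted p = 0.0417). SH3GL3 was well above background on 5 RFIneg, 8 RFIpl and 5 RFIplR arrays, and RFC4 on 4, 7 and 4. In all, 59 probes changed, 42 higher and 17 lower in RFIneg, and the 38 of them with a symbol covered 13 named genes, with 17 probes of CA3 alone.

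Genes of fat synthesis lay higher in RFIneg as a list (median log2 difference 0.63, adjusted p = 0.000524 in camera, and adjusted p = 0.387 with an estimated correlation), although none of the 13 measured members passed the test over all genes or adjusted over the list alone. ACSS2, which makes acetyl-CoA from acetate, had a log2 difference of 0.99 (adjusted p = 0.558), PGD, which supplies NADPH, 0.68 (adjusted p = 0.612), and ELOVL5, a fatty acid elongase, 1.01 (adjusted p = 0.713). The array RFIpl 2, which carried muscle transcripts, lay at -1.76 on this list relative to the other bright arrays, and without it the median was 0.30 (adjusted p = 0.0348, and adjusted p = 0.0633 with brightness as a block). With brightness, slide and scan day as blocks the list had adjusted p = 0.0188, 0.00433 and 0.00327, and within the bright and dim arrays 0.0178 and 0.204.

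The lipolysis list was also higher (median 0.24, adjusted p = 0.00979, and adjusted p = 0.309 with an estimated correlation). Of its 13 members none passed over all genes and 3 rose when adjusted over the list alone. ADORA1, an adenosine receptor, differed by 0.86 (adjusted p = 0.0928), AQP7, a glycerol channel, by 0.79 (adjusted p = 0.134), and LIPE, hormone-sensitive lipase, by 0.55 (adjusted p = 0.244). The list had adjusted p = 0.0433 with brightness, 0.0521 with slide and 0.036 with scan day as a block, 0.165 in the bright arrays and 0.00868 in the dim ones. Adipocyte identity genes were higher (median 0.20, adjusted p = 0.0192, and adjusted p = 0.387 with an estimated correlation), with none of 16 members past the test, also when adjusted over the list alone. ADIPOR2 differed by 0.45 (adjusted p = 0.415), LEP, which encodes leptin, by 1.36 (adjusted p = 0.568), and PLIN1, of the lipid droplet coat, by 0.48 (adjusted p = 0.57). The list had, with brightness, slide and scan day as blocks, adjusted p = 0.0188, 0.267 and 0.175, and within the bright and dim arrays 0.0247 and 0.161.

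The citrate cycle list was higher (median 0.21, adjusted p = 0.0236, and adjusted p = 0.743 with an estimated correlation), with none of 18 members past the test and 1 risen when adjusted over the list alone. Its member PC, pyruvate carboxylase, differed by 0.44 (adjusted p = 0.177) and PDHA1 by 0.38 (adjusted p = 0.75). Blocks for brightness, slide and scan day gave this list adjusted p = 0.0398, 0.809 and 0.666, and within the bright and dim arrays 0.0247 and 0.745. Amino acid metabolism was higher (median 0.37, adjusted p = 0.0358, and adjusted p = 0.535 with an estimated correlation), with none of 22 members past the test over all genes or adjusted over the list alone. BCAT2, of branched-chain amino acid breakdown, differed by 0.53 (adjusted p = 0.487) and ALDH6A1 by 0.75 (adjusted p = 0.726). With the same 3 blocks it had adjusted p = 0.0188, 0.356 and 0.189, and within the bright and dim arrays 0.0102 and 0.575. RFIpl 2 lay at -0.68 on the citrate cycle list and at -0.81 on the amino acid list, and without that array they had adjusted p = 0.0548 and 0.0958.

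Antigen presentation was higher (median 0.27, adjusted p = 0.0192, and adjusted p = 0.387 with an estimated correlation), with none of 19 members past the test over all genes or adjusted over the list alone. CD74, the invariant chain of class II molecules, differed by 0.42 (adjusted p = 0.61) and SLA-DOA by 0.53 (adjusted p = 0.835). Its values with brightness, slide and scan day as blocks were adjusted p = 0.00271, 0.356 and 0.175, and within the bright and dim arrays 0.00376 and 0.0979.

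Cell cycle genes lay lower in RFIneg as a list (median -0.61, adjusted p = 0.000205, and adjusted p = 0.187 with an estimated correlation). None of 13 members passed over all genes and 1 fell when adjusted over the list alone. MCM3 and MCM4, of the replicative helicase, differed by -1.17 (adjusted p = 0.176) and -0.72 (adjusted p = 0.507), and MCM3 was well above background on 4 RFIneg, 8 RFIpl and 4 RFIplR arrays. For this list the blocks brightness, slide and scan day gave adjusted p = 0.00285, 0.00313 and 0.00327, and within the bright and dim arrays 0.00599 and 0.0138. Insulin and IGF signalling was lower (median -0.10, adjusted p = 0.0204, and adjusted p = 0.17 with an estimated correlation), with none of 21 members past the test and 3 fallen when adjusted over the list alone. IGFBP5 differed by -0.94 (adjusted p = 0.0978), AKT1 by -0.62 (adjusted p = 0.295) and IGF2 by -0.42 (adjusted p = 0.314). With the same 3 blocks it had adjusted p = 0.0398, 0.28 and 0.175, and within the bright and dim arrays 0.0968 and 0.0138.

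Collagen and matrix genes were lower (median -0.28, adjusted p = 0.0284, and adjusted p = 0.619 with an estimated correlation), with none of 25 members past the test over all genes or adjusted over the list alone. POSTN, periostin, differed by -0.98 (adjusted p = 0.41) and COL1A2 by -0.62 (adjusted p = 0.691). With brightness, slide and scan day as blocks the list had adjusted p = 0.0188, 0.393 and 0.499, within the bright and dim arrays 0.0724 and 0.0161, and without RFIpl 2 adjusted p = 0.051.

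Markers of tissues that can lie beside fat were lower in RFIneg as well. The keratinocyte list (median -1.69, adjusted p = 0.0192, and adjusted p = 0.309 with an estimated correlation) had 3 measured members, none past the test over all genes or adjusted over the list alone. SFN differed by -1.95 (adjusted p = 0.583) and DSP by -1.69 (adjusted p = 0.997), and DSP was well above background on 6 RFIneg, 6 RFIpl and 5 RFIplR arrays. The arrays RFIpl 7 and 8 held SFN at 5.26 and 3.72, where the other RFIpl arrays lay between -1.99 and -0.97, and DSP at 4.29 and 2.95, where the others lay between -5.12 and -1.15. Without both the list had a median of -0.35 (adjusted p = 0.227). It had, with brightness, slide and scan day as blocks, adjusted p = 0.0647, 0.267 and 0.145, and within the bright and dim arrays 0.0724 and 0.504. The skeletal muscle list was lower (median -1.03, adjusted p = 0.0236, and adjusted p = 0.713 with an estimated correlation), yet none of its 15 members fell and 1 rose, CA3, over all genes and adjusted over the list alone. RFIpl 2 carried muscle transcripts far above the other arrays, with TNNT3 at 7.18 against a mean of -4.04 in the other bright arrays, and RFIpl 1 had the next highest TNNT3, at 1.71. Without RFIpl 2 the muscle list turned to higher in RFIneg in the test (adjusted p = 0.913), at a median of -0.13, and without both arrays it had a median of 0.05 (adjusted p = 0.261). With the same 3 blocks it had adjusted p = 0.0863, 0.096 and 0.139, and within the bright and dim arrays 0.0724 and 0.991.

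Within scan day 1, which held 5 RFIneg and 3 RFIpl arrays, the median difference was -0.67 for cell cycle, 0.10 for lipogenesis, -0.06 for lipolysis, 0.08 for adipocyte identity and 0.19 for antigen presentation. It was -1.78 for keratinocyte markers, -0.19 for insulin signalling, 0.04 for the citrate cycle, -0.16 for muscle, 0.02 for collagen and 0.21 for amino acid metabolism. Within scan day 2, with 2 RFIneg and 4 RFIpl arrays, the same medians were -0.71, 0.32, 0.62, -0.01 and -0.06, then -2.17, -0.09, -0.33, 0.26, 0.23 and -0.21. On day 1 all arrays were bright, while on day 2 both RFIneg arrays and 2 of the 4 RFIpl arrays were dim, so the medians of day 2 mix group with brightness, as do those of 1 slide. The direction of the pooled test was found in 9 of the 11 lists on day 1, in 5 on day 2, in 10 among the dim arrays of day 2 with 2 arrays of each group, and in 5 to 10 on the 5 slides that held both groups. Day 3 and each of these slides held 1 or 2 arrays of a group, so few that no test was run within them. The only RFIpl array of day 3, and of the slide scanned then, was RFIpl 2, which carried muscle transcripts. The medians there were -7.13 for muscle and 2.46 for lipogenesis. The called probes had the direction of the pooled fit, into which the same arrays entered, for 59 of 59 probes on days 1 and 2 and for 58 or 59 on each slide.

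The members that rose over all genes with brightness as a block numbered 1 for lipogenesis, 4 for lipolysis, 5 for adipocyte identity, 3 for antigen presentation, 2 for the citrate cycle and 4 for amino acid metabolism, and adjusted over the list alone 3, 5, 6, 5, 2 and 10. Those that fell numbered 2 for cell cycle, 4 for insulin signalling, 1 for the citrate cycle and 1 for amino acid metabolism, and adjusted over the list alone 2, 4, 1 and 2. For collagen 1 fell over all genes and none adjusted over the list alone, for insulin signalling and muscle 1 rose in each way, and no keratinocyte marker passed.

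Of the fixed panel, FASN, fatty acid synthase, stood at 8.82 ± 0.39 in RFIneg and 8.20 ± 0.97 in RFIpl (SD, n = 8 each, adjusted p = 0.8 in limma), and SCD at 8.43 ± 0.63 and 7.66 ± 1.39 (adjusted p = 0.938). Differences were 0.10 for ACACA, 0.45 for LPL, 0.10 for PNPLA2, -0.07 for PPARG and 0.27 for ADIPOQ, and none passed the test. Without RFIpl 2, which lay low on lipogenic genes, the difference in FASN went from 0.63 to 0.32 and that in SCD from 0.77 to 0.30, ACACA turned to -0.35 and PPARG stood at -0.17.

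In RFIneg against RFIpl, brightness as a block gave 1887 called probes, among them all 59 of the pooled fit, and within the bright arrays 296. With that block and RFIpl 1 and 2 left out it gave 548. The count was 0 in limma with slide as a block (2411 probes at an unadjusted p under 0.05), and within the scan days (2562 and 1036) and the dim arrays (2714), and scan day as a block left 47. With slide and brightness as separate blocks it was 414, among them 54 of the 59, and with their combined levels 0 (5032), while the median size of the change of the 59 probes was 1.87 in the pooled fit, 1.77 with slide and 1.89 with combined levels. Leaving out 1 array moved the pooled count to between 1 (without RFIpl 8) and 283 (without RFIpl 3), and it was 0 after normexp background correction. None of the 35 lists passed with an estimated correlation or in fry, against 11 with the preset one, and other splits of the samples gave up to 22 lists. With brightness as a block and RFIpl 2 left out, the lipolysis and collagen lists had adjusted p = 0.0633, the adipocyte identity, insulin and amino acid lists 0.0632 and the citrate cycle list 0.143.

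**Figure D2:**
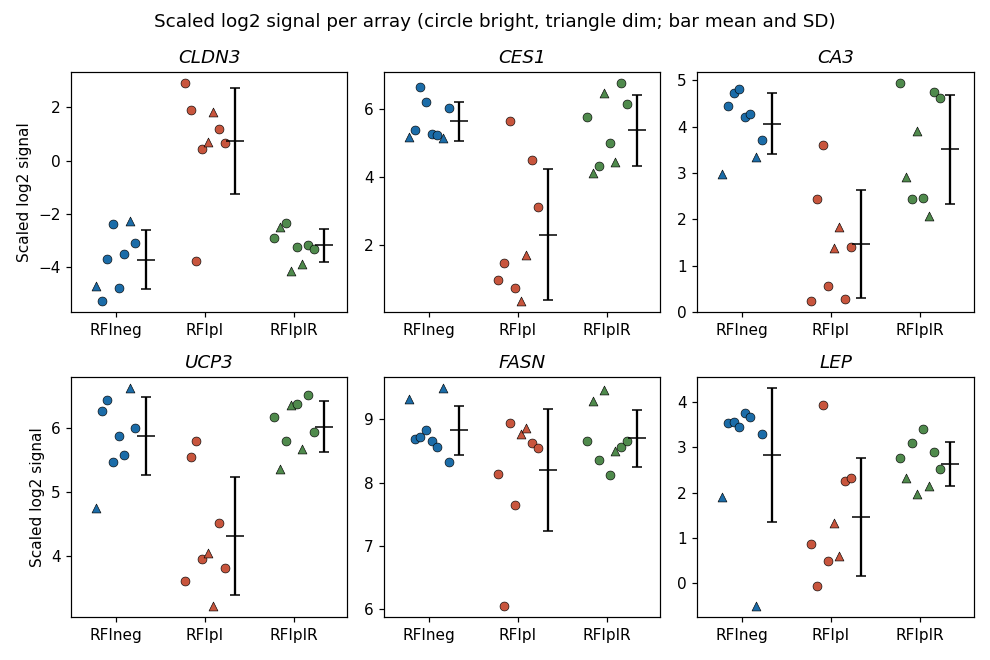
Scaled log2 signal of 6 genes on each array, by group, with circles for bright arrays, triangles for dim arrays and bars for the mean and SD of 8 arrays. CLDN3 averaged 0.73 in RFIpl, -3.72 in RFIneg and -3.18 in RFIplR, with RFIpl 3 at -3.78, and the differences in FASN and LEP did not pass the test.

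At one feeding level, in RFIneg against RFIplR, genes of mitochondrial energy metabolism and fat synthesis lay slightly higher in the low line as lists in camera with its preset correlation, none of them with an estimated one (adjusted p = 0.463 with an estimated correlation for each). No single gene passed the test in limma. The count of called probes was 0 (604 at an unadjusted p under 0.05). It was also 0 with brightness as a block (2713), within the bright arrays (1750), within the dim arrays (2460), with slide as a block (779) and within scan days 1 and 2 (3005 and 270). The smallest p-values among named genes belonged to N4BP2L1, with a log2 difference of -0.74 (SE 0.19, adjusted p = 0.999), LEO1, of the PAF1 transcription complex, with 0.65 (SE 0.19, adjusted p = 0.999), and FXYD2, a regulator of the sodium pump, with 1.27 (SE 0.39, adjusted p = 0.999). FXYD2 was well above background on 7 RFIneg, 7 RFIpl and 3 RFIplR arrays. After normexp background correction its difference was -0.14, where the median of all probes was -0.19. LEO1 was well above background on 8, 8 and 6 arrays.

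Oxidative phosphorylation had a median log2 difference of 0.22 over 28 genes (adjusted p = 1.21e-08, and adjusted p = 0.463 with an estimated correlation), with ATP5A1, of ATP synthase, at 0.43 and NDUFB8, of complex I, at 0.29. Blocks for brightness, slide and scan day gave this list adjusted p = 2.53e-05, 1.04e-07 and 4.82e-06, and within the bright and dim arrays 4.11e-06 and 0.0975. The citrate cycle list had a median of 0.42 over 18 genes (adjusted p = 0.000383, and adjusted p = 0.463 with an estimated correlation), with DLAT and DLD, subunits of pyruvate dehydrogenase, at 0.56 and 0.52. With the same blocks it had adjusted p = 0.00104, 0.0979 and 0.0975, and within the bright and dim arrays 0.0103 and 0.0194. Its median was smaller with these blocks, at 0.25, 0.16 and 0.16.

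De novo lipogenesis had a median of 0.37 over 13 genes (adjusted p = 0.00561, and adjusted p = 0.463 with an estimated correlation), with ACLY, which makes cytosolic acetyl-CoA, at 0.81 and ACSS2 at 0.98. Its values with brightness, slide and scan day as blocks were adjusted p = 0.0142, 0.00182 and 0.00302, and within the bright and dim arrays 0.0103 and 0.198. Glycolysis had a median of 0.31 over 16 genes (adjusted p = 0.018, and adjusted p = 0.463 with an estimated correlation), with PKM, pyruvate kinase, at 0.44 and SLC2A4, the insulin-responsive glucose carrier, at 0.51. With the same blocks it had adjusted p = 0.065, 0.0286 and 0.0805, and within the bright and dim arrays 0.0153 and 0.86. Fatty acid uptake had a median of 0.26 over 14 genes (adjusted p = 0.0272, and adjusted p = 0.463 with an estimated correlation), with CD36 at 0.43 and FABP3 at 0.54. It had adjusted p = 0.0698, 0.367 and 0.128 with the blocks and 0.518 and 0.0319 within the bright and dim arrays.

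Cholesterol synthesis had a median of 0.43 over 14 genes (adjusted p = 0.0272, and adjusted p = 0.463 with an estimated correlation), with NSDHL at 0.78 and MVK, mevalonate kinase, at 0.57. NSDHL was well above background on 8 RFIneg, 8 RFIpl and 5 RFIplR arrays. For this list the blocks brightness, slide and scan day gave adjusted p = 0.0439, 0.0286 and 0.128, and within the bright and dim arrays 0.0103 and 0.86. Antioxidant defence had a median of 0.19 over 26 genes (adjusted p = 0.0342, and adjusted p = 0.463 with an estimated correlation), with GPX3, a secreted glutathione peroxidase, at 0.51. It had adjusted p = 0.0698, 0.126 and 0.106 with the blocks and 0.518 and 0.0194 within the bright and dim arrays. Triglyceride synthesis had a median of 0.16 over 15 genes (adjusted p = 0.0342, and adjusted p = 0.463 with an estimated correlation), with DGAT2, which makes triglyceride, at 0.73. It had adjusted p = 0.428, 0.316 and 0.128 with the blocks and 0.0194 within the dim arrays, and turned to lower within the bright arrays (adjusted p = 0.908). In these 8 lists no member rose or fell over all genes, and none did adjusted over the list alone, in the pooled fit or with brightness as a block. Genes of cytosolic ribosomal proteins passed as a list, with brightness as a block, in the lower direction (median -0.04, adjusted p = 0.0138, and adjusted p = 0.894 with an estimated correlation), where the pooled value was adjusted p = 0.0504 and those within the bright and dim arrays 0.908 and 0.000184, at medians of -0.0020 and -0.11.

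Within scan day 1, with 5 RFIneg and 3 RFIplR arrays, the median difference was 0.29 for oxidative phosphorylation, 0.23 for the citrate cycle, 0.36 for lipogenesis and 0.34 for glycolysis. It was 0.20 for fatty acid uptake, 0.30 for cholesterol synthesis, 0.02 for antioxidant defence and -0.02 for triglyceride synthesis. Within scan day 2, with 2 RFIneg and 4 RFIplR arrays, the same medians were 0.04, -0.18, 0.39 and -0.09, then 0.07, -0.19, -0.06 and 0.21. Both RFIneg arrays of day 2 were dim, against 3 of the 4 RFIplR arrays, so these medians mix group with brightness, as do those of 1 slide. The pooled direction was found in 7 of the 8 lists on day 1, in 4 on day 2, in 8 among the dim arrays of day 2, and in 1 to 8 on the 5 slides that held both groups, each with 1 or 2 arrays of a group.

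Panel genes differed little, with FASN at 0.12, SCD at 0.01, LPL at 0.21, LEP at 0.19, ADIPOQ at 0.08 and IGF2 at -0.02. The sign of LEP turned with scan day as a block (-0.18), that of ADIPOQ with brightness as a block (-0.021), and that of IGF2 after normexp (0.27). In RFIneg against RFIplR 5 of the 35 lists passed with brightness as a block, 4 of them among the 8 of the pooled test. With an estimated correlation or in fry 0 passed, and other splits of the samples gave up to 15 lists.

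**Figure D3:**
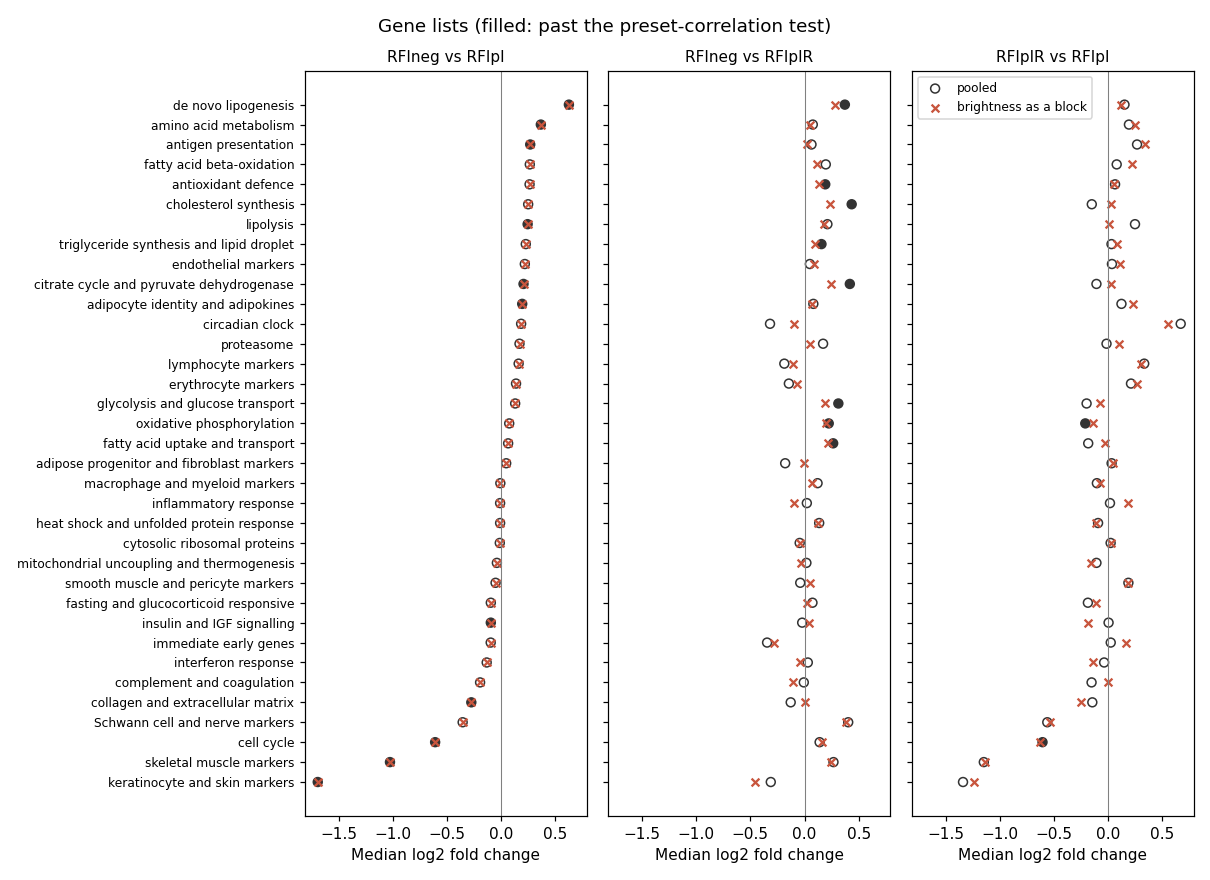
Median log2 fold change of each of 35 gene lists in the 3 comparisons, with circles for the pooled values (filled where the list passed the camera test) and crosses for values with brightness as a block. In RFIneg against RFIpl 11 lists passed, in RFIneg against RFIplR 8 and in RFIplR against RFIpl 2, and none passed with an estimated correlation.

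Within the high line, in RFIplR against RFIpl, the lower feeding level went with more CYP2A19, a cytochrome P450, more CES1 and more SNCG, which encodes gamma-synuclein, and with less CLDN3. CYP2A19 rose by 3.55 (SE 0.67, adjusted p = 0.02) from a mean of -1.55 ± 2.09 (SD, n = 8) in RFIpl. CES1 rose by 3.07 (SE 0.63, adjusted p = 0.0349), to 5.38 ± 1.04 (SD, n = 8), and SNCG by 2.24 (SE 0.48, adjusted p = 0.0455). SNCG averaged 0.02 in RFIneg, near its 0.18 in RFIplR and above its -2.06 in RFIpl. CYP2A19, at another probe, rose by 2.65 in RFIneg against RFIpl with brightness as a block (adjusted p = 0.0165 in limma). In the pooled fit 0 of its 7 probes passed there. The difference between the comparisons is RFIneg against RFIplR, where the count of called probes was 0 in limma, pooled and with brightness as a block. No difference between the comparisons was thus found for either change, which does not show that the changes were equal. CLDN3 fell by 3.92 (SE 0.66, adjusted p = 0.0133), to -3.18 ± 0.62 (SD, n = 8), while its other kept probe was not called and changed by only -0.40.

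CA3 rose by 1.94 (adjusted p = 0.0472), MYOC by 1.81 (adjusted p = 0.0393), S100A12 by 1.80 (adjusted p = 0.0472), UCP3 by 1.72 (adjusted p = 0.0254) and FHL1 by 1.43 (adjusted p = 0.00762). S100A12 was the 1 risen member of 23 in the inflammatory list (adjusted p = 0.334 as a list), and UCP3 the 1 of 13 in the uncoupling list (adjusted p = 0.994). SH3GL3 fell by 1.49 (adjusted p = 0.0137), P311 by 1.31 (adjusted p = 0.0135) and PEX11A, of peroxisome division, by 1.20 (adjusted p = 0.0303). LEO1 fell by 0.86 (adjusted p = 0.0482) and PDXK, pyridoxal kinase, by 0.71 (adjusted p = 0.0492). RFC4 fell by 1.22 (adjusted p = 0.0228). Its difference turned to 0.29 after normexp background correction, where the median of all probes was 0.20. Each of these genes lay beyond the RFIpl mean in 8 of 8 RFIplR arrays, which their choice from the same arrays favours. In all, 85 probes changed, 52 higher and 33 lower in RFIplR, and the 32 with a symbol covered 20 named genes. Only 1 of the 20 kept probes of CA3 was called here, and 2 of 7 each of CES1 and CYP2A19. All kept probes of these genes had the same sign.

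Cell cycle genes were lower in RFIplR as a list (median -0.61, adjusted p = 7.97e-05, and adjusted p = 0.22 with an estimated correlation). None of the 13 members passed over all genes and 4 fell when adjusted over the list alone, with MCM3 at -1.31 (adjusted p = 0.0832), MCM4 at -0.83 (adjusted p = 0.265) and CCNB1, cyclin B1, at -1.24 (adjusted p = 0.337). MCM3 had a difference of 0.34 after normexp, where the median of all probes was 0.20. CCNB1 was well above background on 7 RFIneg, 8 RFIpl and 5 RFIplR arrays. With brightness, slide and scan day as blocks the list had adjusted p = 0.00153, 0.000278 and 0.000253, and within the bright and dim arrays 0.053 and 0.00115. Oxidative phosphorylation was lower (median -0.21, adjusted p = 0.033, and adjusted p = 0.84 with an estimated correlation), with none of 28 members past the test over all genes or adjusted over the list alone, and with NDUFC1 at -0.35 (adjusted p = 0.475) and CYCS, cytochrome c, at -0.41 (adjusted p = 0.595). In the fit with brightness as a block 2 cell cycle members fell over all genes and 5 adjusted over the list alone, and no oxidative phosphorylation member passed. The latter list had adjusted p = 0.137, 0.00395 and 0.0411 with the blocks and 0.125 and 0.0894 within the bright and dim arrays. The medians of both lists were -0.32 and -0.33 within scan day 1, with 3 arrays of each group. Within scan day 2, with 4 of each, they were -1.18 and -0.24. Dim arrays of day 2 numbered 3 in RFIplR and 2 in RFIpl, and among them the medians were -0.98 and -0.21. On day 3, with 1 of each, they were 0.32 and 0.47, and the RFIpl array there was RFIpl 2, which carried muscle transcripts. Without RFIpl 3 oxidative phosphorylation had adjusted p = 0.108, and without RFIpl 7 and 8 adjusted p = 0.345.

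Antigen presentation passed as a list with brightness as a block (median 0.34, adjusted p = 0.00153, and adjusted p = 0.435 with an estimated correlation), with 8 of 19 members risen over all genes and 9 adjusted over the list alone, where the pooled value was adjusted p = 0.108. In fry 3 lists passed, circadian clock (adjusted p = 0.00425), cell cycle (adjusted p = 0.0299) and insulin and IGF signalling (adjusted p = 0.0299). The circadian list had a median of 0.67 and adjusted p = 0.175 in camera. The insulin list had a median difference of 0.01, a mean of -0.16 and a lower direction in camera (adjusted p = 0.108). Panel values that did not pass included FASN at 0.50, SCD at 0.76, LEP at 1.17 (adjusted p = 0.605) and IGF2 at -0.39 (adjusted p = 0.285), and without RFIpl 2 FASN stood at 0.20 and SCD at 0.28.

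In RFIplR against RFIpl, brightness as a block gave 2950 called probes, among them all 85 of the pooled fit, or 1906 with RFIpl 1 and 2 left out, and within the bright arrays 933. With slide as a block the count was 25, with scan day 258, with slide and brightness as separate blocks 1687 and with their combined levels 512. Within scan days 1 and 2 it was 0 in limma (5126 and 973 probes at an unadjusted p under 0.05), and within the dim arrays 0 (5028). The called probes had the direction of the pooled fit, into which the same arrays entered, for 85 of 85 on days 1 and 2 and for 81 to 85 on the 5 slides that held both groups, and day 2 and 2 of the slides mix group with brightness. Leaving out 1 array moved the pooled count to between 22 (without RFIpl 1) and 296 (without RFIpl 3), and it was 4 after normexp background correction. Other splits of the samples gave up to 18 lists past camera, against 2.

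The median, the mean and the direction in camera of a list differed in sign, in the pooled fit, only for lists that did not pass. In RFIneg against RFIpl these were the endothelial, inflammatory, progenitor, uncoupling and smooth muscle lists, in RFIneg against RFIplR the inflammatory, uncoupling, complement, interferon and fasting lists, and in RFIplR against RFIpl the insulin, uncoupling, triglyceride and endothelial lists. With slide or scan day as a block the insulin list in RFIneg against RFIpl had a median of 0.02 with a lower direction in camera, and with scan day the collagen list had 0.02, also with a lower direction.

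CLDN3, CES1, CA3, MYOC, S100A12, UCP3, FHL1, SH3GL3, RFC4 and P311 were called in the same direction in both comparisons with RFIpl. The array RFIpl 3 lay at 0.959 on a scale where 0 is the mean of the other RFIpl arrays and 1 the mean of RFIneg and RFIplR. That scale used the probes called without it in the same direction in both comparisons, with brightness as a block. Of all called probes 19 were higher and 11 lower in both, where independent lists would share 0.0763 and 0.0196. Simulated unchanged groups compared with 1 simulated RFIpl group shared 0. That simulation held no change that could be called, so its count of shared calls decides nothing. With brightness as a block 765 were higher and 373 lower in both, against 71.1 and 29.9. Across probes, which are not independent replicates, the fold changes correlated at r = 0.680, against 0.502 for the simulated groups. The covariance was 0.102 against 0.101 simulated. With the RFIpl arrays split into sets of 4, r had a median of 0.352 over 70 splits. With brightness as a block r was 0.782 against 0.499, the covariance 0.113 against 0.023, and the median over split RFIpl arrays 0.513. In the simulation all probes and arrays varied independently, unlike the real ones, so it varies less than real samples can. Other splits of the real samples gave r of up to 0.965, and up to 0.743 with brightness as a block. RFIneg against RFIpl and RFIneg against RFIplR shared 0 calls in limma, since the latter had 0 calls (604 at an unadjusted p under 0.05). A test of any difference among the groups called 79 probes, and 2584 with brightness as a block.

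**Figure D4:**
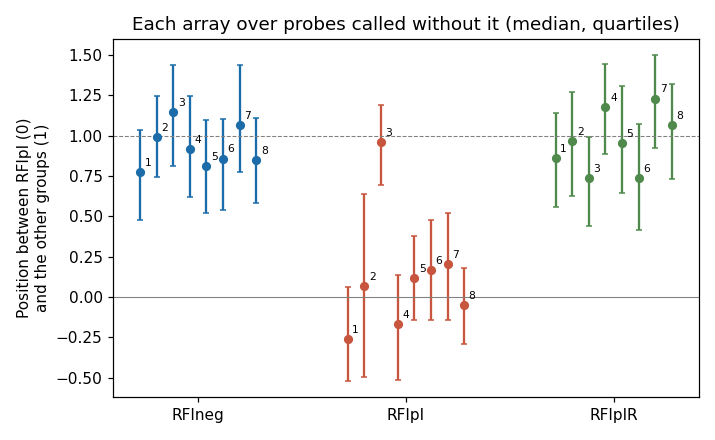
Position of each array, numbered by replicate, on a scale where 0 is the mean of the other RFIpl arrays and 1 the mean of RFIneg and RFIplR. Points are medians and bars quartiles. The probes were those called without the array shown, in the same direction in both comparisons with RFIpl, with brightness as a block. RFIpl 3 lies at 0.959 and the other RFIpl arrays between -0.262 and 0.204.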

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

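All tests in this part on why RFIpl stands apart, on RFIpl 3 and on muscle in RFIpl 2 were chosen only after the result was seen, while the counts over other splits of the samples were set before their results were seen.

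The number of probes called was set against 100 splits of the samples into groups of the same sizes, the real one included. For RFIneg against RFIpl 1 of 100 splits gave as many calls (59 in the real split, 4 in the highest other). With brightness as a block it was 1 of 100 (1887 and 1), so chance is unlikely. It is not excluded, since 1 of 100 is the smallest share that 100 splits can give. In RFIplR against RFIpl 2 of 100 gave as many (85 and 15566), and with the block 1 of 100 (2950 and 311), so chance is unlikely there too. For any group difference it was 2 of 100 (79 and 10400), and chance is unlikely. In RFIneg against RFIplR the count was 0 in limma, in the pooled fit (604 at an unadjusted p under 0.05, highest other 14873) and with the block (2713, highest other 47), which all 100 of 100 splits reach by construction, so the splits decide nothing there. The splits with 14873 and 15566 calls put all 5 dim arrays of the compared groups on one side, so they point to the brightness of the arrays, a structure of the samples, and the values with brightness as a block stand beside them.

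For the gene lists past camera, chance cannot be excluded in any comparison. For RFIneg against RFIpl 16 of 100 splits gave as many lists (11 in the real split, 22 in the highest other), and with brightness as a block 52 of 100 (9 and 22). In RFIneg against RFIplR it was 15 of 100 (8 and 15), and 54 with the block (5 and 22). In RFIplR against RFIpl it was 84 of 100 (2 and 18), and 99 with the block (2 and 19). Nor can it be excluded for the correlation of the fold changes in both comparisons with RFIpl, with 44 of 100 splits as high (0.680, highest other 0.965). These splits mix bright and dim arrays. With brightness as a block and splits within the brightness classes it was 1 of 100 (0.782 and 0.743), so chance is unlikely for the blocked value. For the shared calls of both comparisons with RFIneg the splits decide nothing, since the real value was 0 in limma (604 probes at an unadjusted p under 0.05 in RFIneg against RFIplR), which 100 of 100 reach (highest other 0).

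RFIpl stood apart from both other groups, and brightness as the whole cause is argued against by 933 probes called within the bright arrays alone for RFIplR against RFIpl. Whether the difference also lies in the dim arrays cannot be told apart from its lying in the bright arrays alone, since 85.1% of these probes had the same sign in the dim arrays, against 71.28% in the highest other of the 10 splits of the 5 dim arrays, too few for a share under 0.05. Slide as the cause for RFIplR against RFIpl is argued against by 1687 calls with slide and brightness as separate blocks and 512 with their combined levels, and muscle in RFIpl 2, or in RFIpl 1 and 2, as the whole cause by 3110 and 1906 calls with brightness as a block and those arrays left out. For RFIneg against RFIpl, slide beside brightness is argued against as the whole cause by 414 calls with separate blocks, among them 54 of the 59 pooled ones, while an effect of slide that differs with brightness cannot be told apart from the groups, since combined levels left 0 calls (5032 at an unadjusted p under 0.05) as the median SE of the 59 went from 0.35 to 0.41 and the residual degrees of freedom from 21 to 12, at median sizes of 1.87 and 1.89. The lower feed intake that RFIneg and RFIplR share, with free access in RFIpl, stays open as a hypothesis that may account for the pattern, and was not tested.

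RFIpl 3 did not lie with its group. The probes used were the 2029 called without it, with brightness as a block, in the same direction in both comparisons with RFIpl. Over them its median position was 0.959 between the other RFIpl arrays (0, range -0.262 to 0.204) and the other groups (1). A wrong label or a swap with a sample outside the series could give this position. A swap with an array of RFIneg or RFIplR is argued against by the lowest position there, 0.738, and poor hybridisation by a median correlation of 0.981 with the bright arrays. That this pig differed from the others of its group stays open and was not tested, so the array stays in its group throughout.

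RFIpl 2 held muscle transcripts, with 12 of 15 measured genes of the muscle list highest on that array among all 24, which is consistent with skeletal muscle in the sample. MYLPF stood at 8.74, ACTA1 at 8.52, CKM at 7.60 and TNNT3 at 7.18, while CA3, which fat cells also express, was at 5.62 against a mean of 5.98 in the other bright arrays. A shift of the whole array, which scaling would hide, is argued against before scaling by a median deviation of -0.59 from the other bright arrays over the genes outside the muscle list (quartiles -0.90 and -0.28), where the muscle list had quartiles of 4.98 and 8.90. No biological explanation was tested, since the design names none for a single array.

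A value far from the other arrays of its group was found in 30 of 321 groups of values, where chance gives about 1 in 20 groups, 16.05 here. RFIpl 2 accounted for 6. On that array TTN stood at 4.24 (next array -1.01) and TNNT1 at 3.81 (-2.52), while the lipogenic genes FASN at 6.05 (7.65), ACACA at -0.80 (1.92), SCD at 4.35 (7.54) and ACLY at 3.39 (6.58) lay below the rest. RFIpl 3 accounted for 4, with CLDN3 at -3.78 (0.43), SH3GL3 at -3.20 (-2.03), AQP7 at 1.03 (0.30) and IGFBP5 at 2.39 (3.28). The spike-in signal of RFIpl 4 was 997.74, against 487.52 on the next array.

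Of the arrays below, RFIneg 1 and 7 and RFIplR 2 and 4 are dim, and each group was tested over its bright and dim arrays. In RFIneg, array 7 had LEP at -0.51 (next array 1.91), PLIN1 at 3.28 (2.55) and PC at 8.21 (7.95). Array 8 had LEO1 at -1.84 (-1.30), ACLY at 6.19 (7.24) and FITM2 at -1.28 (-0.41). Array 3 had S100A8 at 2.44 (1.34) and FN1 at -0.56 (3.94). TNNT1 was -1.52 on array 5 (-3.13), COL1A2 was 8.26 on array 1 (7.41) and LPL was 6.43 on array 4 (6.10). In RFIplR, PLK1 was -1.70 (-3.73) and LEO1 -2.78 (-1.98) on array 4, COL1A2 5.69 (6.94) and FXYD2 -6.48 (-4.56) on array 7, MOCS1 0.58 on array 3 (1.31), ACACA 0.77 on array 8 (2.13), GPX3 4.48 on array 2 (5.87) and ATP5I 6.13 on array 1 (5.80).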

How the results depend on the processing

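The fits with brightness as a block, with slide and brightness together or within a brightness class or scan day, and those that leave out RFIpl 2, RFIpl 3 or RFIpl 1 and 2 with brightness as a block, were chosen after seeing the data, as were the list tests that leave out RFIpl 2, RFIpl 3, RFIpl 1 and 2 or RFIpl 7 and 8, and the other alternatives were chosen beforehand. Counts below are probes called in RFIneg against RFIpl, RFIplR against RFIpl and for any group difference (59, 85 and 79 in the pooled fit), and the cause of a change was not tested unless stated.

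They were 0, 4 and 0 in limma after normexp (1256, 2437 and 1808 at an unadjusted p under 0.05), 3, 21 and 16 with median scaling, 2, 38 and 25 with no filter on dim probes, and 3001, 2938 and 4058 with array weights, which called 4 in RFIneg against RFIplR. Slide as a block gave 0, 25 and 0 (2411, 2628 and 2279 unadjusted). A fit of only the groups compared gave 0 and 26 in the pairs (1882 and 2063 unadjusted). Brightness as a block gave 1887, 2950 and 2584, bright arrays only 296, 933 and 479, and dim arrays only 0, 0 and 0 (2714, 5028 and 4048 unadjusted), where only 7 arrays remain. Slide and brightness gave 414, 1687 and 972 as separate blocks and 0, 512 and 0 as combined levels (5032, 5852 and 5638 unadjusted). With brightness as a block the counts were 1477, 3110 and 2284 with RFIpl 2 left out, 548, 1906 and 1175 with RFIpl 1 and 2 left out and 3400, 3671 and 3736 with RFIpl 3 left out. An adjusted p under 0.01 left 0, 4 and 3, and an unadjusted p under 0.01 gave 695, 910 and 747, and 108 in RFIneg against RFIplR, by construction of the threshold. RFIplR against RFIpl moved to 134 with probes well above background on all 24 arrays, RFIneg against RFIpl to 39 in the deposited table of processed values, and scan day as a block gave 258 and 121 for RFIplR against RFIpl and any difference. Quantile scaling (50, 113 and 81) and a trended, robust variance (63, 88 and 80) stayed within 1.5 times.

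The share of higher calls was 71.2% in RFIneg against RFIpl and 61.2% in RFIplR against RFIpl, and in other scalings 0% of 3 (median scaling), 87.2% of 39 (deposited table) and, in RFIplR against RFIpl, 25% of 4 (normexp). Under normexp the median of all probes was -0.19 in RFIneg against RFIplR and 0.20 in RFIplR against RFIpl, where the pooled values were -0.011 and 0.012.

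The replicate number as a block gave 0, 2 and 2 calls in limma (1533, 1850 and 1456 unadjusted). The labels state no pairing by number, and no strong shared signal was seen. Same-numbered arrays correlated above 0.1 in 12 of 24 pairs (-0.819 to 0.879). With brightness removed it was 3 of 24, and 2 of 24 arrays correlated best with their own number. Such correlations cannot exclude a pairing in the design. No list lost its call under this block.

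Lists past camera (11, 8 and 2 in RFIneg against RFIpl, RFIneg against RFIplR and RFIplR against RFIpl) numbered 0, 0 and 0 with an estimated correlation and 0, 0 and 3 in fry. In RFIneg against RFIpl they numbered 2 with slide, 3 with scan day, 6 in bright arrays, 7 with RFIpl 2 left out and 18 with RFIpl 7 and 8 left out. In RFIneg against RFIplR they numbered 14 with normexp, 4 with scan day and 5 with brightness as a block. Of the 8 pooled lists there, 2 passed with scan day and 4 with brightness. In RFIplR against RFIpl they numbered 12 with normexp, 4 with no filter, 4 with RFIpl 1 and 2 left out, and 1 in bright arrays and with RFIpl 3 left out. The muscle list in RFIneg against RFIpl turned its direction with RFIpl 2 left out (adjusted p = 0.913), the array with the highest values of 12 of its 15 genes, and with RFIpl 1 and 2 left out (0.261), and the triglyceride list in RFIneg against RFIplR in bright arrays (adjusted p = 0.908). The correlation of the fold changes against RFIpl was 0.296 with normexp (0.680 pooled).

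Differences that did not pass in the pooled fit and turned sign in RFIneg against RFIplR were FXYD2 -0.14 and IGF2 0.27 (normexp), PNPLA2 -0.11, ADIPOQ -0.092 and IGF2 0.063 (bright arrays), ADIPOQ -0.10 (slide), -0.071 (scan day) and -0.021 (brightness) and LEP -0.18 (scan day). In RFIplR against RFIpl they were MCM3 0.34, LPL -0.058 and ADIPOQ -0.13 (normexp), and PNPLA2 0.0125 (slide), 0.0134 (brightness) and 0.17 (bright arrays). ADIPOQ did pass in RFIplR against RFIpl with brightness as a block. Of the genes called in the pooled fit RFC4 turned sign, to 0.29 (normexp). Among the largest changes of the fit with brightness as a block, ISM1 turned to 0.43 and PID1 to 0.35 (normexp). Of the 27 calls of named genes, 27 were kept with brightness as a block, 25 with scan day, 22 in bright arrays, 18 with quantile scaling, 3 with slide, 1 with normexp and 0 in limma with the replicate number as a block, and 26 of 27 had the same sign with normexp and 27 in the other settings named here. The deposited table held 23 of them, of which 18 were kept and 23 had the same sign.

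Leaving out each array gave 1 to 283 calls in RFIneg against RFIpl, 0 to 0 in RFIneg against RFIplR, 22 to 296 in RFIplR against RFIpl and 3 to 264 for any difference. RFIneg against RFIpl moved by over 1.5 times without RFIneg 2 (5), 3 (2), 4 (2), 5 (4), 6 (2) and 8 (3) and without RFIpl 1 (3), 3 (283), 4 (5), 5 (4), 7 (13) and 8 (1). RFIplR against RFIpl moved without RFIneg 2 (53), 3 (48), 4 (49) and 5 (54), RFIpl 1 (22), 3 (296), 4 (38), 5 (41), 6 (51), 7 (50) and 8 (28), and RFIplR 1 (55), 2 (53), 4 (33), 5 (28), 7 (32) and 8 (54). Any difference moved without RFIneg 2 (47), 3 (41), 4 (41), 5 (51) and 6 (48), RFIpl 1 (6), 3 (264), 4 (9), 5 (14), 7 (24) and 8 (3), and RFIplR 5 (52). With brightness as a block the counts stayed between 1008 and 3400, and 1993 and 3671, and RFIneg against RFIplR reached 55 without RFIneg 8, 5 without RFIplR 8 and 2 without RFIneg 7.

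Signal over background limits the dim arrays and the genes measured above background on only some arrays of a group, such as CLDN3, SH3GL3, RFC4 and MCM3. The bright arrays of 1 slide, with 2 RFIneg, 1 RFIplR and no RFIpl array, had 52.1%, 57.0% and 57.1% of probes well above background. The dim arrays had 43.1% to 61.5%. Arrays with low detection were therefore unevenly spread over the groups. Lists were not run with array weights, median scaling or the deposited table.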

Other observations

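The genes in this part, apart from LIPE, IGF2 and ADIPOQ of the fixed panel, were chosen after their values were seen. The changes below are from the fit with brightness as a block, which was itself added after seeing the data, and in the pooled fit none of them passed. CLDN4, a tight junction protein like CLDN3, fell by 3.04 on the log2 scale in RFIneg (adjusted p = 0.00447 in limma) and by 2.48 in RFIplR (adjusted p = 0.00894) against RFIpl, and was well above background on 3 RFIneg, 7 RFIpl and 3 RFIplR arrays. RBP5, a retinol-binding protein, fell by 2.38 in both comparisons (adjusted p = 0.0345 and 0.0222), at different probes, and its probe in RFIplR was well above background on 7 of 8 RFIplR arrays. CYP4F2, a cytochrome P450 that hydroxylates fatty acids, fell by 1.69 in RFIneg (adjusted p = 0.0371) and by 2.19 in RFIplR (adjusted p = 0.00688), with 6 of 8 RFIplR arrays well above background. SDR16C5, a retinol dehydrogenase, rose by 2.30 in RFIneg (adjusted p = 0.00154) and by 2.25 in RFIplR (adjusted p = 0.000397). KLKB1, which encodes plasma prekallikrein, rose by 2.58 (adjusted p = 0.00668) and 2.62 (adjusted p = 0.00395), and was well above background on 6 RFIneg, 5 RFIpl and 5 RFIplR arrays. Within the bright arrays RBP5 (adjusted p = 0.0981 in RFIneg and 0.155 in RFIplR) and CYP4F2 (0.223 and 0.0968) did not pass in limma. CLDN4, SDR16C5 and KLKB1 passed there in both comparisons.

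Some genes were taken from that fit in 1 comparison. The difference between the comparisons is RFIneg against RFIplR, where the count of called probes was 0 in that fit. No difference in their change was thus found, which does not show that the changes were equal. UCHL1, a ubiquitin hydrolase, rose by 2.50 in RFIneg against RFIpl (adjusted p = 0.00361, and 0.0634 within the bright arrays), with 6 of 8 RFIpl arrays well above background. UGT1A6, a glucuronosyltransferase, rose by 2.03 in RFIplR against RFIpl (adjusted p = 0.00601, and 0.041 within the bright arrays). Of the panel, LIPE rose by 0.55 in RFIneg against RFIpl (adjusted p = 0.019). IGF2 fell by 0.42 in RFIneg (adjusted p = 0.032) and by 0.40 in RFIplR (adjusted p = 0.03) against RFIpl. ADIPOQ, which encodes adiponectin, rose by 0.27 (adjusted p = 0.0392) and 0.29 (adjusted p = 0.0211), but had a difference of -0.13 in RFIplR after normexp.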
